A study of Homo sapiens with 12 samples.

How the data were processed

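RNA from human squamous carcinoma xenografts was measured on 12 Affymetrix HG-U133A arrays, 3 in each of 4 groups: resistant and sensitive tumours, each untreated or 5 hours after 3 Gy. Per the labels, each array was labelled from 6 µg of total RNA and carried a pool of 3 RNA samples. The deposited values are signal intensities on a linear scale, computed by the authors with MAS5 per the submitters' processing notes, which give no version. From the values, each array had been scaled by the authors to a 2% trimmed mean of 500 (500.14 to 500.16 over the 12 arrays), and no value was missing. No further scaling was applied.

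The analysis started from these intensities. Of 22283 probe sets, 68 Affymetrix controls were left out, as were the 40% of the other 22215 with the lowest mean log2 signal, which left 13329 whose mean signal was at least 120.5. The supplied annotation gave 1 gene symbol for 19065 of the 22215 probe sets, several for 1043 and none for 2107. Probe sets with several symbols or none were tested but name no gene. A gene was represented by its tested probe set with the highest mean, which gave 8215 genes. The GRCh38.p14 gene table was used only for names and for which genes neighbour each other.

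Signals were transformed to log2(signal + 16) and fitted with limma 3.58.1 in R 4.3.3, as 1 model with a mean per group over all 12 arrays and empirical Bayes moderation with an intensity trend. The 5 comparisons were resistant minus sensitive in untreated and in irradiated tumours, irradiated minus untreated in each tumour, and the difference of these responses. Tests were two-sided, adjusted by the Benjamini-Hochberg method over the 13329 probe sets, and called at an adjusted p under 0.05. No replicate numbers were paired, since the labels tie no number to a shared animal or day. Arrays with the same number deviated from their group means with correlations of -0.27 to 0.16. The same-number pairs of resistant and sensitive irradiated arrays had 0.16, 0.11 and 0.12, and a replicate block was run as an alternative.

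Fixed gene lists, 31 in number, were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 31 lists. They cover interferon-stimulated genes, a published interferon-related list from this pair of tumours, MHC class I, interferon-gamma responses, p53 targets, double-strand break repair, other DNA repair, G1/S, G2/M, histones, immediate early genes, NF-kappaB targets, apoptosis, NRF2 targets, hypoxia, glycolysis, oxidative phosphorylation, the unfolded protein response, heat shock proteins, cholesterol biosynthesis, keratinocyte differentiation, basal and simple epithelial genes, mesenchymal and invasion genes, growth factor receptors, ribosomal proteins, the proteasome, and markers of 5 sets of other cell types (fibroblast, endothelium, macrophage, lymphocyte, and muscle, fat, red cell and nerve). Camera was repeated with a correlation estimated for each list, and fry was run, which tests whether the genes of a list move 1 way on balance. The members of each list were also adjusted over the list alone. These lists, the model, the threshold, the rule for named genes and most alternatives were set before the data were examined.

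The genes named are the 10 largest rises and 10 largest falls per comparison among called genes whose 3 arrays per group did not overlap, up to 4 called members with the smallest adjusted p of each list that was called or had 3 or more called members, and IRF9, ISG15, CDKN1A and MDM2 in any case. The prose gives a selection of the list members this rule takes. A pair of other genes in that fixed set has no probe set named in the supplied annotation and is not reported here. Where no gene was called, the 5 with the smallest p are given as values.

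The precision rests on 3 arrays per group: the median SE was 0.18 log2 units, and 0.26 for the difference of responses. A background was taken on each array as the 95th percentile of 27 bacterial control probe sets, a rule chosen after the data were seen. Where all 3 arrays of a group lay below it, the difference is given as a fold bound against it, though genes were ranked by the fitted difference. Where only some did, their number is given. The code was tested on simulated data with the real means and spreads and 200 changed probe sets per set, over 5 sets per comparison. In the comparison of untreated tumours 24.8% of 1.5-fold, 65.4% of 2-fold and 93.9% of 4-fold changes were called, and in that of irradiated tumours 30.7%, 63.9% and 95.5%. With the adjusted threshold these shares depend on how many probe sets change, and fewer than 200 were not tried. A list shifted by 0.5 was found in 5 of 5 sets in each comparison, with 0 false calls in 150 other list tests. Simulated genes were independent, so this does not test the correlation between genes. The shift of 0.5 is larger than every list median called after irradiation or in the difference of responses. Whether shifts of that smaller size are found was not tested.

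The alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a filter of 60%, only the 6 arrays compared, a prior variance without trend or robust, array weights, the mean of all probe sets of a gene, no probe sets ending in _x_at or _s_at, a fold threshold of 1.5, the replicate block, chip lot as a block, and each array left out in turn. Chip lot and scan order came from the scanner information files, and a pause of over 60 minutes separated 2 scan runs. Chip lot 2 held sensitive irradiated arrays 2 and 3. Scan run 2 held sensitive untreated array 3 and all sensitive irradiated arrays. The scan run block, the log2 ACTB 3' to 5' ratio as a covariate, and leaving out resistant untreated array 2 with resistant irradiated array 1 were added after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.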

Results

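Gene expression was measured in human squamous carcinoma tumours grown as xenografts in nude mice. The sensitive tumours grew from SCC-61, a head and neck squamous carcinoma cell line, and the resistant tumours from nu61, a radioresistant line derived from it. Tumours of 150 to 200 mm3 were left untreated or were irradiated with 3 Gy and taken 5 hours later. The 12 Affymetrix HG-U133A arrays fell into 4 groups of 3, and each array carried a pool of 3 RNA samples. The labels do not say whether the 3 pools of a group shared RNA, so every p-value measures only the spread between these arrays. The number of arrays, 3 per group, limits the precision. Median signals lay between 177 and 235, and the correlation of log2 signals was 0.947 to 0.968 within groups and 0.925 to 0.960 between the tumours. The ratio of 3' to 5' signal of ACTB, a measure of RNA integrity, averaged 1.71 ± 0.43 in the resistant untreated, 2.06 ± 0.31 in the resistant irradiated, 1.94 ± 0.28 in the sensitive untreated and 1.65 ± 0.23 in the sensitive irradiated arrays (SD, n = 3). Signals below are means ± SD of 3 arrays, and differences are in log2 units ± SE.

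The untreated arrays address which genes differed between the resistant and the sensitive tumours before radiation. Genes that cells switch on in response to interferon were higher in the resistant tumours. Of 48 measured interferon-stimulated genes, 45 were higher and none was lower, or 47 higher when adjusted over the list alone. Their median difference was 1.70 (camera adjusted p = 1.4e-66; adjusted p = 0.00019 with an estimated correlation). IFI44L, an interferon-induced gene, had a signal of 3819 ± 299 in the resistant and 114 ± 16.6 in the sensitive tumours, a difference of 4.89 ± 0.22 (limma adjusted p = 1.3e-09). ISG15, a ubiquitin-like modifier, had signals of 12628 ± 1198 and 1486 ± 109, a difference of 3.07 ± 0.14 (adjusted p = 2.1e-09). BST2, which tethers budding virus to the cell, was higher by 3.35 ± 0.17, and CXCL10, a chemokine that attracts T cells, by 3.28 ± 0.14. The antiviral genes RSAD2 (1 of 3 sensitive arrays at the background), DDX60, IFIT1, IFI44, HERC6, IFIT3 and MX1 were higher by 2.62 to 3.14, and LAMP3 by 2.77. In each of these genes all 3 resistant arrays lay above all 3 sensitive arrays. IRF9, the DNA-binding subunit of the interferon-activated transcription factor, was higher by 0.74 ± 0.12 (adjusted p = 0.0013). All 6 measured members of a published list of interferon-related genes from this pair of tumours were higher, and all 6 when adjusted over the list alone, with a median difference of 2.81 (camera adjusted p = 1.0e-18; adjusted p = 0.0052 with an estimated correlation). That list was chosen on these tumours and is not independent evidence, and its 6 members are also among the 48 interferon-stimulated genes.

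Genes of antigen presentation stood higher in the same arrays. Of 18 genes of MHC class I and antigen processing, 8 were higher and none was lower, or 10 higher when adjusted over the list alone (median 0.41, camera adjusted p = 2.7e-06; adjusted p = 0.026 with an estimated correlation). They included HLA-F (1.16 ± 0.10), the immunoproteasome subunit PSMB9 (1.06 ± 0.12), the peptide transporter TAP1 (1.10 ± 0.14) and HLA-G (0.89 ± 0.10). Of 18 interferon-gamma response genes, 5 were higher and none lower, both over all genes and when adjusted over the list alone (median 0.28, adjusted p = 0.0013; adjusted p = 0.051 with an estimated correlation). Among them were WARS1, a tryptophanyl-tRNA synthetase (1.27 ± 0.13), and GBP1, an interferon-induced GTPase (0.95 ± 0.18). The inflammatory list of 23 NF-kappaB targets and cytokines had 6 members higher and 2 lower, or 7 and 3 when adjusted over the list alone (median 0.40, adjusted p = 0.039; adjusted p = 0.11 with an estimated correlation). Leaving out resistant untreated array 1 or 3 or sensitive untreated array 2 or 3 ended this call (medians 0.31 to 0.44, adjusted p 0.055 to 0.11). CXCL1, a neutrophil chemokine, was higher by 1.58 ± 0.25 and NFKB1 by 0.86 ± 0.15, while the inhibitor NFKBIA differed by -0.64 ± 0.09 and the interleukin-1 antagonist IL1RN by -0.78 ± 0.12.

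Cell cycle genes were also higher in the untreated resistant tumours. Of 57 G2/M and mitosis genes, 27 were higher and none lower, or 37 higher when adjusted over the list alone (median 0.49, camera adjusted p = 1.8e-16; adjusted p = 0.014 with an estimated correlation). FOXM1, a transcription factor of mitotic genes, had a signal of 804 ± 103 in the resistant and 321 ± 62.1 in the sensitive tumours (1.29 ± 0.18, limma adjusted p = 0.00018). The kinetochore motor CENPE (0.98 ± 0.15), the survivin gene BIRC5 (0.68 ± 0.11) and the spindle gene NUSAP1 (0.60 ± 0.10) were higher too. Of 40 genes of G1/S and DNA replication, 7 were higher and none lower, or 10 higher when adjusted over the list alone (median 0.34, adjusted p = 8.2e-06; adjusted p = 0.020 with an estimated correlation), among them the clamp loader subunit RFC4 (0.70 ± 0.13) and the ribonucleotide reductase subunit RRM2 (0.57 ± 0.11). Of 37 double-strand break repair genes, 4 were higher and none lower, both over all genes and when adjusted over the list alone (median 0.18, adjusted p = 0.037; adjusted p = 0.073 with an estimated correlation). The call ended without resistant untreated array 2 or 3 or sensitive untreated array 2 (0.15 to 0.19, adjusted p 0.057 to 0.063). These 4 were RPA3, a subunit of the single-strand binding protein (1.14 ± 0.13), FANCI (0.76 ± 0.18), the helicase BLM (0.59 ± 0.15) and NBN (0.45 ± 0.13). Histone genes differed the other way, though only 14 of the 48 on the list were tested. Of 14, 3 were lower and none higher, or 6 lower when adjusted over the list alone (median -0.46, adjusted p = 0.00012; adjusted p = 0.081 with an estimated correlation), with H2AC6 at -0.91 ± 0.13, H2BC5 at -0.77 ± 0.14 and H2BC12 at -0.51 ± 0.13. Their median was -0.23 when no dim probe sets were left out (adjusted p = 0.0034).

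Genes of the maturing squamous epithelium were lower in the untreated resistant tumours. Of 44 keratinocyte differentiation genes, 27 were lower and none higher, or 35 lower when adjusted over the list alone, with a median of -0.86 (camera adjusted p = 6.9e-23; adjusted p = 0.053 with an estimated correlation). SPRR3, a cornified envelope protein, had a signal of 311 ± 206 in the resistant and 10562 ± 2120 in the sensitive tumours (-5.22 ± 0.66, limma adjusted p = 9.1e-05). KRT76, an epithelial keratin, had 25.3 ± 4.85 and 2716 ± 479. All 3 resistant arrays were at the background, so the gene was at least 29.8-fold lower. LORICRIN (-3.07 ± 0.42, 1 of 3 resistant arrays at the background) and FLG (-2.71 ± 0.33), both structural proteins of cornified cells, KRT13 (-1.83 ± 0.19), the desmosomal cadherin DSC1 (-1.20 ± 0.11), the lipoxygenase ALOX12B (-1.56 ± 0.15) and the protease KLK7 (-1.93 ± 0.19) were lower as well. Other large differences were PDLIM4 (-4.25 ± 0.40, 1 of 3 resistant arrays at the background), CEACAM5 (-3.53 ± 0.37, called on 1 of its 2 probe sets, the other without the same sign), MAL (-3.18 ± 0.25) and SUSD4 (-2.71 ± 0.33, also 1 of 3). AADAC was at least 6.08-fold lower. Of 32 basal and simple epithelial genes, 4 were higher and 8 lower, or 4 and 13 when adjusted over the list alone (median -0.17, adjusted p = 0.019; adjusted p = 0.055 with an estimated correlation), with KRT15 at -0.91 ± 0.11, RAB25 at -1.01 ± 0.15 and DSG2 at 0.99 ± 0.18. This call ended without resistant untreated array 2 (-0.16, adjusted p = 0.072). Of 28 mesenchymal and invasion genes, 7 were higher and none lower, or 9 and 1 when adjusted over the list alone (median 0.31, adjusted p = 0.00045; adjusted p = 0.19 with an estimated correlation). INHBA, a subunit of activin (1.18 ± 0.15), the matrix metalloproteinase MMP13 (1.18 ± 0.18) and the TGF-beta-induced matrix protein TGFBI (0.91 ± 0.16) were among them.

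Metabolic lists differed too. Of 19 cholesterol biosynthesis genes, 5 were lower and none higher, or 7 lower when adjusted over the list alone (median -0.34, camera adjusted p = 2.5e-05; adjusted p = 0.026 with an estimated correlation), among them the sterol reductases TM7SF2 (-2.77 ± 0.44, 2 of 3 resistant arrays at the background) and DHCR7 (-0.79 ± 0.17). Of 32 oxidative stress and NRF2 target genes, 3 were higher and 9 lower, or 3 and 11 when adjusted over the list alone (median -0.29, adjusted p = 0.0013; adjusted p = 0.026 with an estimated correlation). The aldehyde dehydrogenase ALDH3A1 differed by -1.54 ± 0.20, whereas SLC7A11, the cystine transporter, was higher by 1.49 ± 0.18. Of 24 hypoxia response genes, 2 were higher and 6 lower, or 2 and 7 when adjusted over the list alone (median -0.17, adjusted p = 0.015; adjusted p = 0.37 with an estimated correlation), with PFKFB3 at -1.50 ± 0.26, MXI1 at -0.79 ± 0.12 and CA12 at 0.51 ± 0.10. This call ended without resistant untreated array 2 (-0.14, adjusted p = 0.062) or sensitive untreated array 1 (-0.05, adjusted p = 0.12), and the median was -0.26 without sensitive untreated array 2 or 3. In the irradiated tumours it had the other sign (0.16, adjusted p = 0.59). Of 30 proteasome genes, 5 were higher and none lower, or 10 higher when adjusted over the list alone (median 0.16, adjusted p = 0.00084; adjusted p = 0.19 with an estimated correlation), PSMA4 by 0.52 ± 0.10. Of 47 cytosolic ribosomal protein genes, 3 were lower, and none when adjusted over the list alone (median -0.14, adjusted p = 0.0028; adjusted p = 0.68 with an estimated correlation). That call ended without resistant untreated array 1 or 3 or sensitive untreated array 3 (-0.09 to -0.07, adjusted p 0.061 to 0.082), and the median was -0.24 without resistant untreated array 2.

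The remaining lists were not called in the untreated arrays. The p53 targets (27 genes, 3 higher and 3 lower, or 6 and 3 when adjusted over the list alone) had a median of 0.09 (camera adjusted p = 0.37). CDKN1A, the cyclin-dependent kinase inhibitor p21, differed by -0.45 ± 0.10 (limma adjusted p = 0.0067), and the death receptor FAS by 0.72 ± 0.18 (adjusted p = 0.017). All 5 probe sets of MDM2, the p53 antagonist, were among the dimmest and were not tested, the brightest with signals of 63.0 ± 11.2 and 79.2 ± 16.6. Base and nucleotide excision and mismatch repair (median 0.01, adjusted p = 0.51), immediate early genes (-0.12, 0.43), apoptosis regulators (0.12, 0.069), glycolysis (0.03, 0.99), oxidative phosphorylation (0.08, 0.39), the unfolded protein response (0.05, 0.27), heat shock proteins (0.05, 0.9997) and growth factor receptor signalling (0.01, 0.9997) were not called either. At most 8 members of any of these lists were called, over all genes or when adjusted over the list alone. In the last of these, the receptor genes IGF1R (1.02 ± 0.17) and ERBB2 (-0.78 ± 0.15) went opposite ways. EGFR differed by -0.96 ± 0.24 on 1 of its 3 probe sets, but by 0.19 (adjusted p = 0.69) when the probe sets ending in _x_at and _s_at were left out. In the unfolded protein response list, TRIB3 (0.81 ± 0.10), ATF4 (0.40 ± 0.09) and the asparagine synthetase ASNS (1.20 ± 0.28) were higher. The markers of other cell types had medians of 0.22 (fibroblast and matrix, adjusted p = 0.27), -0.29 (endothelium and pericyte, 0.9997, with a mean of 0.09), 0.28 (macrophage and myeloid, 0.43), 0.09 (lymphocyte, 0.9997) and 0.08 (muscle, fat, red cell and nerve, 0.9997, with a mean of -0.02). Host cells of these xenografts are mouse cells, which human probe sets see only by cross-hybridisation. The 50 markers tested had a median signal of 214.9, and their lists do not measure host cells directly.

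Over all genes, limma called 1563 of 13329 probe sets between the untreated tumours, 768 higher and 795 lower in the resistant. Those called included the representative probe sets of 1084 genes. Of the called probe sets, 1054 differed at least 1.5-fold. With an unadjusted p under 0.05 there were 3484, where chance alone gives 666. Of the 31 lists, camera called 17, and 7 with an estimated correlation. The arrays were scanned in 2 runs. Within scan run 1 (3 resistant and 2 sensitive arrays) 905 probe sets were called and the interferon-stimulated genes had a median of 1.69. The call of the ribosomal protein list was not kept there (median -0.07, adjusted p = 0.058), nor that of the NF-kappaB list with scan run as a block (0.33, adjusted p = 0.080), while the hypoxia list had -0.26 within the run (adjusted p = 0.0058).

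**Figure D1:**
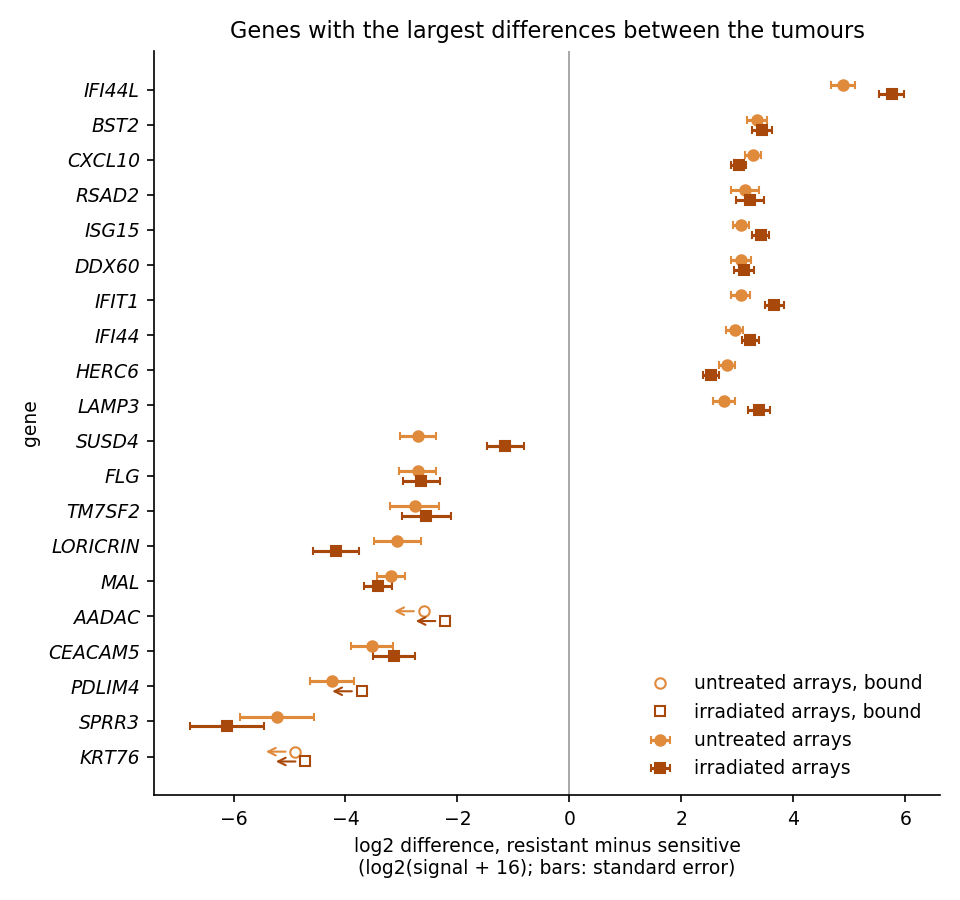
Difference between the resistant and the sensitive tumours (horizontal axis, log2 units, resistant minus sensitive; points are limma estimates and bars their SE, n = 3 arrays per group) for the 10 genes with the largest rises and the 10 with the largest falls in the untreated arrays. Orange circles show the untreated and brown squares the irradiated arrays. Open symbols with an arrow are bounds, for genes at the background on all 3 arrays of a group (KRT76 and AADAC in both, PDLIM4 in the irradiated arrays). Each gene lay on the same side of 0 in both, ISG15 for example at 3.07 and 3.42. CEACAM5 is shown by 1 of its 2 probe sets, and the other did not share its sign.

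The irradiated arrays address which genes differed between the tumours 5 hours after 3 Gy. Interferon-stimulated genes were again higher in the resistant tumours, 45 of 48 and none lower, or all 48 when adjusted over the list alone, with a median of 1.79 (camera adjusted p = 2.5e-62; adjusted p = 0.00025 with an estimated correlation). IFI44L had signals of 4001 ± 213 and 62.2 ± 29.7, with 2 of 3 sensitive arrays at the background (5.76 ± 0.22, limma adjusted p = 1.5e-10). MX1, an antiviral GTPase, had signals of 8855 ± 509 and 1130 ± 120 (2.96 ± 0.10, adjusted p = 4.1e-11), and ISG15 was higher by 3.42 ± 0.14, IFIT1 by 3.66 ± 0.17, BST2 by 3.44 ± 0.17 and LAMP3 by 3.38 ± 0.20. IRF9 was higher by 0.96 ± 0.12. The published list of 6 was higher in all 6 members, also when adjusted over the list alone (median 3.10, adjusted p = 8.8e-18; adjusted p = 0.0057 with an estimated correlation), again without being independent evidence. Of 18 MHC class I genes, 8 were higher and none lower, or 12 when adjusted over the list alone (median 0.53, adjusted p = 4.9e-08; adjusted p = 0.015 with an estimated correlation), with PSMB8 at 1.30 ± 0.13 and PSMB9 at 1.22 ± 0.12. Of 18 interferon-gamma response genes, 7 were higher and none lower, both over all genes and when adjusted over the list alone (median 0.44, adjusted p = 9.3e-05; adjusted p = 0.024 with an estimated correlation), GBP1 by 1.77 ± 0.18.

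Cell cycle and epithelial genes differed after irradiation as well. Of 57 G2/M and mitosis genes, 18 were higher and none lower, or 28 when adjusted over the list alone (median 0.42, camera adjusted p = 4.2e-10; adjusted p = 0.024 with an estimated correlation), among them cyclin A2 (CCNA2, 1.08 ± 0.16) and the phosphatase CDC25B (0.73 ± 0.12). Of 40 G1/S genes, 9 were higher and none lower, or 12 when adjusted over the list alone (median 0.33, adjusted p = 9.1e-05; adjusted p = 0.024 with an estimated correlation), with cyclin E2 (CCNE2) at 0.81 ± 0.19. Histone genes were lower in 6 of 14 and higher in none, or lower in 9 when adjusted over the list alone (median -0.67, adjusted p = 0.00041; adjusted p = 0.12 with an estimated correlation; -0.29 and adjusted p = 0.0013 when no dim probe sets were left out). Keratinocyte differentiation genes were lower in 28 of 44 and higher in none, or lower in 34 when adjusted over the list alone (median -0.87, adjusted p = 3.6e-25; adjusted p = 0.038 with an estimated correlation). SPRR3 had signals of 246 ± 330 and 10675 ± 3926 (-6.12 ± 0.66, limma adjusted p = 1.5e-05), and LORICRIN differed by -4.17 ± 0.42, each with 2 of 3 resistant arrays at the background. KRT76 was at least 26.3-fold lower, PDLIM4 at least 13.1-fold, the serpin SERPINB7 at least 8.19-fold, cornulin (CRNN), an epidermal differentiation protein, at least 7.12-fold and AADAC at least 4.66-fold. ELF5, an epithelial transcription factor, differed by -3.16 ± 0.50, with 2 of 3 resistant arrays at the background. Of 32 basal and simple epithelial genes, 6 were higher and 9 lower, or 7 and 12 when adjusted over the list alone (median -0.20, adjusted p = 0.011; adjusted p = 0.038 with an estimated correlation), with RAB25 at -1.38 ± 0.15 and the cell adhesion gene EPCAM at 1.15 ± 0.14. Mesenchymal and invasion genes were higher in 14 of 28 and lower in none, or higher in 16 when adjusted over the list alone (median 0.51, adjusted p = 1.9e-08; adjusted p = 0.053 with an estimated correlation), among them TGFBI (1.47 ± 0.16), MMP13 (1.39 ± 0.18), INHBA (1.36 ± 0.15) and MMP10 (1.05 ± 0.14).

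Cholesterol biosynthesis genes were lower in 12 of 19 and higher in none, with the same counts when adjusted over the list alone (median -0.51, camera adjusted p = 1.9e-08; adjusted p = 0.0099 with an estimated correlation). DHCR7 differed by -1.15 ± 0.17, and SCD, a fatty acid desaturase that the list also holds, by -1.57 ± 0.19. NRF2 targets were lower in 16 of 32 and higher in 2, both over all genes and when adjusted over the list alone (median -0.38, adjusted p = 7.5e-07; adjusted p = 0.0057 with an estimated correlation), with ALDH3A1 at -2.19 ± 0.20, the aldo-keto reductase AKR1B10 at -1.05 ± 0.11 and SLC7A11 at 1.19 ± 0.18. Ribosomal protein genes were lower in 5 of 47, both over all genes and when adjusted over the list alone (median -0.14, adjusted p = 5.2e-05; adjusted p = 0.57 with an estimated correlation), RPL10A by a difference of -0.54 ± 0.09. Without resistant irradiated array 2 the median was -0.09 (adjusted p = 0.0021). Of 15 fibroblast and matrix markers, 4 were higher and 1 lower, or 5 and 1 when adjusted over the list alone (median 0.31, adjusted p = 0.044; adjusted p = 0.25 with an estimated correlation). Lumican (LUM) was higher by 1.21 ± 0.13 and COL1A1 by 0.73 ± 0.19, while decorin (DCN) differed by -1.03 ± 0.19. Whether tumour cells or cross-hybridising mouse cells gave these signals was not tested. The fibroblast call ended without resistant irradiated array 1 or 3 or sensitive irradiated array 1 or 2 (0.21 to 0.46, adjusted p 0.055 to 0.093). The p53 targets were not called (median 0.02, adjusted p = 0.89), with CDKN1A at -0.56 ± 0.10 (adjusted p = 0.0012), FAS at 1.22 ± 0.18 and the death receptor TNFRSF10B at 0.88 ± 0.19. Of the NF-kappaB list, also not called (median 0.31, adjusted p = 0.12), CXCL1 was higher by 2.25 ± 0.25 (1 of 3 sensitive arrays at the background) and interleukin-6 (IL6) by 1.26 ± 0.25. Immediate early genes (median -0.02, mean 0.09, adjusted p = 0.97) and the proteasome (median -0.02, mean 4.8e-05, adjusted p = 0.93) were not called. Hypoxia response genes, lower in the untreated resistant tumours, had a median of 0.16 here, with 3 higher and 1 lower, or 5 and 3 when adjusted over the list alone (adjusted p = 0.59). The other 12 lists that were not called had adjusted p-values between 0.15 and 0.89.

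In the irradiated arrays limma called 1924 of 13329 probe sets, 875 higher and 1049 lower in the resistant tumours, and 3871 had an unadjusted p under 0.05. Those called included the representative probe sets of 1231 genes. Camera called 14 lists, and 10 with an estimated correlation. No array was shared between the comparisons of untreated and of irradiated tumours. Of the probe sets called in both, 885 in number, 882 differed in the same direction: 427 were higher in both, where 50.4 would be by chance, and 455 lower in both, where 62.6 would be. These expected numbers treat the calls as independent. The shared fit gives a probe set the same SE in both comparisons, so they may be too low. Over all probe sets, which are not independent replicates, the differences correlated with Pearson's r = 0.66 and Spearman's rho = 0.54. All 3 sensitive irradiated arrays were scanned in run 2 and all resistant arrays in run 1, so no within-run value exists. With scan run as a block 222 probe sets were called, with chip lot as a block 892, and within chip lot 1 (3 resistant and 1 sensitive array) 832. With 1 sensitive array the spread comes from the other groups, and the scan run block rests on the 1 sensitive untreated array of run 2. Under the scan run block the interferon-stimulated genes had a median of 1.62 (adjusted p = 5.1e-64) and the keratinocyte list -1.01 (adjusted p = 2.7e-22), while the ribosomal list (-0.01, adjusted p = 0.53) and the fibroblast list (0.31, adjusted p = 0.44) were not called. Under the chip lot block the fibroblast (0.38, adjusted p = 0.085) and the basal and simple epithelial list (-0.21, adjusted p = 0.053) were not, whereas the ribosomal list had -0.26 (adjusted p = 2.4e-07), larger than over all arrays, and the MHC class I list 0.31 (adjusted p = 1.2e-05), smaller than over all arrays.

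**Figure D2:**
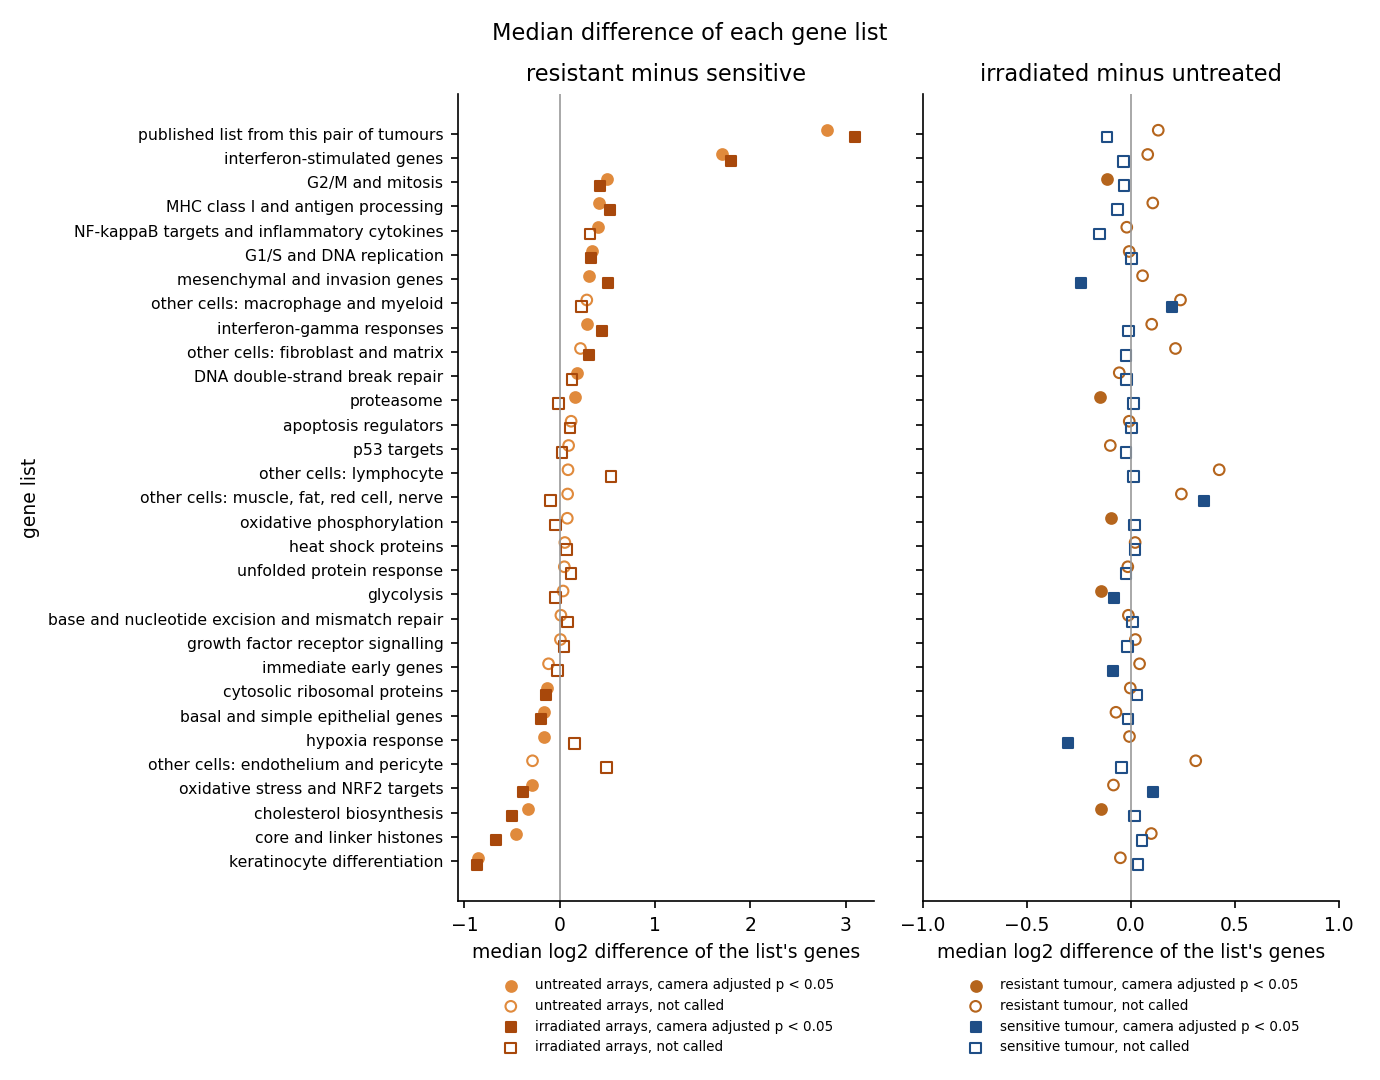
Median log2 difference (horizontal axes) of the genes of each fixed list (rows). The left panel gives resistant minus sensitive tumours in the untreated (circles) and the irradiated arrays (squares) and the right panel irradiated minus untreated arrays in the resistant (circles) and the sensitive tumours (squares); filled symbols are called by camera, with adjusted p under 0.05, and the scales of the panels differ. The interferon-stimulated genes lay at 1.70 and 1.79 on the left, and the hypoxia response of the sensitive tumours at -0.30 on the right.

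The resistant tumours with and without radiation address what 3 Gy changed in them after 5 hours. KIZ, a centrosomal protein gene, was the single probe set called by limma of 13329. Its signal was 633 ± 90.0 in the irradiated and 1305 ± 134 in the untreated arrays (-1.03 ± 0.14, adjusted p = 0.034), and 1912 probe sets had an unadjusted p under 0.05. Camera called 5 lists, all lower after irradiation, in none of which a member was called over all genes. Proteasome genes had a median of -0.15, with 26 of 30 below 0 and 1 higher and 9 lower when adjusted over the list alone (adjusted p = 5.4e-06; adjusted p = 0.38 with an estimated correlation). G2/M and mitosis genes had a median of -0.11, with 2 of 57 lower when adjusted over the list alone (adjusted p = 0.0064; adjusted p = 0.51 with an estimated correlation), and cholesterol biosynthesis genes -0.14, with 3 of 19 lower when adjusted over the list alone (adjusted p = 0.017; adjusted p = 0.38 with an estimated correlation). Glycolysis (-0.14, adjusted p = 0.013; adjusted p = 0.39 with an estimated correlation) and oxidative phosphorylation (-0.10, adjusted p = 0.019; adjusted p = 0.54 with an estimated correlation) had no member lower when adjusted over the list alone. Of these calls only that of the proteasome was kept with any 1 array left out. Without resistant irradiated array 1, which stood apart, G2/M (-0.10, adjusted p = 0.28) and glycolysis (-0.11, adjusted p = 0.096) were not called, nor oxidative phosphorylation without resistant untreated array 2, which also did (-0.05, adjusted p = 0.38). Without both arrays G2/M (-0.06, adjusted p = 0.50), glycolysis (-0.16, adjusted p = 0.054) and oxidative phosphorylation (-0.05, adjusted p = 0.50) were not called. Cholesterol biosynthesis was not without resistant untreated array 1 (-0.15, adjusted p = 0.067) or resistant irradiated array 2 (-0.13, adjusted p = 0.071). Medians moved to -0.18 for G2/M without resistant untreated array 1, to -0.08 for glycolysis without resistant untreated array 3, and to -0.22 for cholesterol biosynthesis without resistant irradiated array 1. The ACTB 3' to 5' ratio was 2.06 ± 0.31 in these irradiated and 1.71 ± 0.43 in the untreated arrays.

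The p53 targets were not called in the resistant tumours (median -0.10, camera adjusted p = 0.28), with CDKN1A at -0.11 ± 0.10 (limma adjusted p = 0.62). Interferon-stimulated genes had a median of 0.08 (adjusted p = 0.16), with ISG15 at 0.08 ± 0.14 and IRF9 at 0.06 ± 0.12. DNA double-strand break repair (median -0.06, adjusted p = 0.30) and the lymphocyte (0.43, adjusted p = 0.21), endothelium (0.31, adjusted p = 0.35), macrophage (0.24, adjusted p = 0.39), fibroblast (0.21, adjusted p = 0.28) and muscle, fat, red cell and nerve markers (0.24, adjusted p = 0.056) were not called. On simulated data for this comparison 63.6% of 2-fold and 26.3% of 1.5-fold changes were recovered. Resistant untreated array 2 and resistant irradiated array 1 stood apart from their groups. Leaving out the first gave 105 called probe sets, KIZ among them, and leaving out both gave 29 without KIZ, whose call was lost in 16 of 27 other settings. All 6 arrays shared 1 chip lot and 1 scan run.

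The sensitive tumours with and without radiation address the same question. Hypoxia response genes were lower as a group after irradiation, with a median of -0.30, 21 of 24 below 0 and 10 lower when adjusted over the list alone, though none over all genes (camera adjusted p = 1.9e-15; adjusted p = 0.081 with an estimated correlation). The genes with the smallest p-values, none of which passed the limma test, included HK2, a glycolytic hexokinase, with signals of 1665 ± 282 in the irradiated and 2979 ± 474 in the untreated arrays (-0.84 ± 0.16, adjusted p = 0.47). They also included BNIP3, a hypoxia-induced mitochondrial protein (802 ± 119 and 1479 ± 369, -0.85 ± 0.17), the collagen hydroxylase P4HA1 (-0.53 ± 0.12), the growth factor BMP2 (-0.55 ± 0.12) and the muscarinic receptor CHRM3, whose irradiated arrays were at the background. Mesenchymal and invasion genes had a median of -0.24, with 27 of 28 below 0 and none called when adjusted over the list alone (adjusted p = 4.0e-08; adjusted p = 0.24 with an estimated correlation). Glycolysis (median -0.08, with 4 of 19 lower when adjusted over the list alone, adjusted p = 0.029; adjusted p = 0.48 with an estimated correlation) and immediate early genes (-0.09, with 1 of 29 lower when adjusted over the list alone, adjusted p = 0.018; adjusted p = 0.50 with an estimated correlation) were called lower. The glycolysis call ended without sensitive untreated array 3 or sensitive irradiated array 1 or 3 (-0.09 to -0.02, adjusted p 0.057 to 0.19). That of the immediate early genes ended without sensitive untreated array 1 or sensitive irradiated array 1 (both -0.05, adjusted p 0.28 and 0.56), and their median was -0.14 without sensitive untreated array 2 and -0.13 without sensitive irradiated array 2.

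On the other side, markers of muscle, fat, red cells and nerve were higher after irradiation, with a median of 0.35 and 10 of 11 above 0 (camera adjusted p = 0.00086; adjusted p = 0.27 with an estimated correlation). Macrophage and myeloid markers had 0.20 and 7 of 8 above 0 (adjusted p = 0.029; adjusted p = 0.50 with an estimated correlation), 2 of these markers, S100A8 and S100A9, being keratinocyte genes as well. Neither marker list shows a change in host cells, which are mouse cells and are seen only by cross-hybridisation. NRF2 targets had 0.11 and 24 of 32 above 0 (adjusted p = 0.037; adjusted p = 0.24 with an estimated correlation). None of these 3 lists had a member called, also when adjusted over the list alone. The muscle call depended on sensitive irradiated array 1, without which it ended (0.27, adjusted p = 0.13), and the median was 0.57 without sensitive untreated array 3. The macrophage call ended without sensitive untreated array 2 or sensitive irradiated array 1 or 3 (0.18 to 0.22, adjusted p 0.091 to 0.13), and the NRF2 call without sensitive untreated array 1 or 3 or sensitive irradiated array 1 or 2 (0.06 to 0.08, adjusted p 0.073 to 0.18). The p53 targets had a median of -0.02 (adjusted p = 0.84), and CDKN1A had signals of 4069 ± 67.9 and 4073 ± 38.6. Interferon-stimulated genes had a median of -0.03 (adjusted p = 0.27), with ISG15 at -0.26 ± 0.14 and IRF9 at -0.16 ± 0.12 (limma adjusted p = 0.9998 for both). Limma called 0 of 13329 probe sets, with 596 at an unadjusted p under 0.05 where chance gives 666, and camera 7 lists, of which 0 with an estimated correlation. On simulated data for this comparison 64.8% of 2-fold changes were recovered. Within chip lot 1 (1 irradiated and 3 untreated arrays) the hypoxia list had a median of -0.47 and within scan run 2 (3 and 1) -0.32. With 1 array on a side the spread comes from the other groups, so these values exclude no difference between batches. In scan run 2 the mesenchymal (-0.12, adjusted p = 0.087), immediate early (-0.10, 0.33), muscle (0.09, 0.30), macrophage (0.21, 0.27) and NRF2 lists (0.09, 0.20) were not called, and in chip lot 1, where sensitive irradiated array 1 is the irradiated one and the muscle list had 0.74, glycolysis (-0.06, 0.35), the macrophage (0.24, 0.12) and NRF2 lists (0.06, 0.35) were not. Medians further from 0 than over all arrays were -0.18 for the immediate early genes in chip lot 1 and -0.16 for glycolysis in scan run 2, both called.

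**Figure D3:**
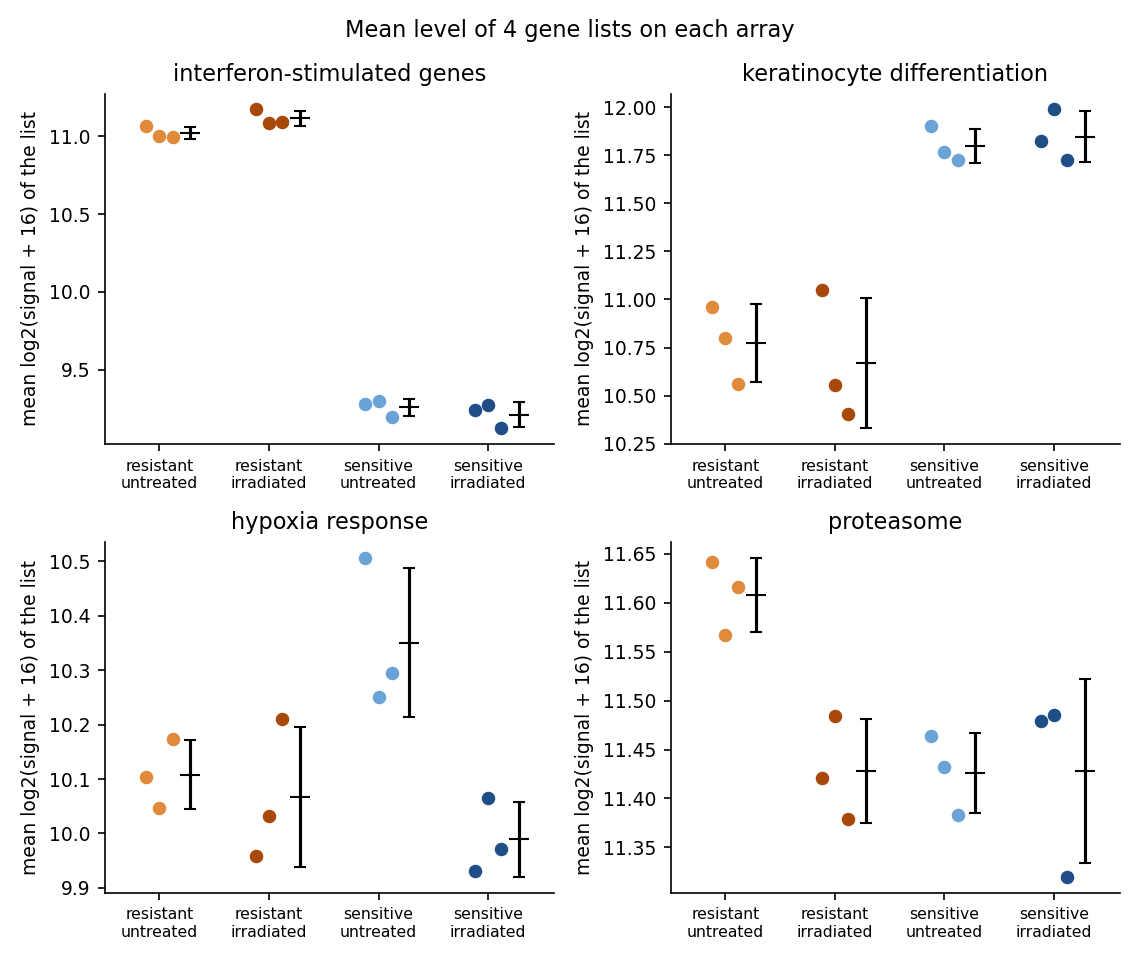
Mean level of 4 gene lists on each array (vertical axes, mean log2(signal + 16) of the tested genes, with axes that do not start at 0), by group (horizontal axis; points are arrays, bars the mean ± SD, n = 3). Interferon-stimulated genes averaged 11.02 and 11.12 in the resistant and 9.26 and 9.21 in the sensitive groups, and hypoxia response genes 10.35 in the sensitive untreated against 9.99 in the sensitive irradiated arrays.

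The difference of the irradiation responses, resistant minus sensitive, addresses whether radiation changed the tumours differently. Camera called 9 lists on this difference. Hypoxia response genes had a median difference of 0.30 (adjusted p = 0.00015; adjusted p = 0.46 with an estimated correlation) and mesenchymal and invasion genes 0.32 (adjusted p = 0.0016; adjusted p = 0.51 with an estimated correlation), both with lower medians in the sensitive response. Proteasome genes had -0.19, with 3 of 30 lower when adjusted over the list alone (adjusted p = 0.00015; adjusted p = 0.46 with an estimated correlation), a call lost with the ACTB ratio as a covariate (-0.14, adjusted p = 0.054), NRF2 targets -0.21 (adjusted p = 0.0050; adjusted p = 0.21 with an estimated correlation), oxidative phosphorylation -0.12 (adjusted p = 0.022; adjusted p = 0.58 with an estimated correlation), cholesterol biosynthesis -0.17 (adjusted p = 0.032; adjusted p = 0.46 with an estimated correlation), lost with the covariate as well (-0.18, adjusted p = 0.11), and keratinocyte differentiation -0.12 (adjusted p = 0.044; adjusted p = 0.77 with an estimated correlation). Interferon-stimulated genes had 0.13, with 34 of 48 above 0 and none called when adjusted over the list alone (adjusted p = 0.033; adjusted p = 0.61 with an estimated correlation). The published list had 0.31 in 6 of 6 members, not as independent evidence (adjusted p = 0.023; adjusted p = 0.51 with an estimated correlation). The mean level of the proteasome list was 11.61 in the resistant untreated arrays and 11.43 in each other group. That of the hypoxia list was 10.35 in the sensitive untreated arrays, and 10.11, 10.07 and 9.99 in the other groups. For each list, its calls in the untreated tumours, after irradiation and in this difference share 1 untreated group, which stood highest. They are not separate evidence. With any 1 array left out only the hypoxia, NRF2 and proteasome calls were kept. The mesenchymal call ended without resistant untreated array 2 (0.31, adjusted p = 0.067), and its median was 0.21 without resistant irradiated array 3. That of oxidative phosphorylation ended without resistant untreated array 2 (-0.05, adjusted p = 0.31) or sensitive irradiated array 2 (-0.12, adjusted p = 0.082). The cholesterol call ended without resistant untreated array 1, resistant irradiated array 2, sensitive untreated array 2 or sensitive irradiated array 2 (-0.17 to -0.11, adjusted p 0.087 to 0.15). The keratinocyte call was kept only without resistant untreated array 3, resistant irradiated array 1, sensitive untreated array 1 or sensitive irradiated array 3, with a median of -0.22 without the second of these, and without the others the median lay between -0.12 and 0.024 (adjusted p 0.089 to 0.60). The interferon-stimulated and published calls ended without resistant untreated array 3, resistant irradiated array 1, sensitive untreated array 1 or 2 or sensitive irradiated array 3, and the former also without resistant untreated array 2 (0.10 to 0.14, adjusted p 0.069 to 0.33, and 0.23 to 0.29, adjusted p 0.063 to 0.12). Apart from the proteasome list, 1 NRF2 target passed when adjusted over the list alone and no member of the other 7 lists did.

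No single gene passed the test of the difference. Limma called 0 of 13329 probe sets, with 1258 at an unadjusted p under 0.05. The smallest adjusted p over all probe sets was 0.21. Among the probe sets that represent a gene, the smallest p-values belonged to COPE, a coatomer subunit (-1.46 ± 0.27), the zinc finger genes ZNF264 (1.06 ± 0.21) and ZNF160 (0.96 ± 0.19), the glutaredoxin GLRX3 (-0.76 ± 0.15) and HAUS2, an augmin subunit (1.24 ± 0.25), each with an adjusted p of 0.25. ISG15 had 0.34 ± 0.20 (adjusted p = 0.63), IRF9 0.23 ± 0.18 (adjusted p = 0.72) and CDKN1A -0.11 ± 0.14 (adjusted p = 0.85). The responses of the tumours correlated over all probe sets, which are not independent replicates, with Pearson's r = 0.056 and Spearman's rho = 0.045. On simulated data for this comparison 32.8% of 2-fold and 83.6% of 4-fold differences were recovered. Within chip lot 1, with 1 sensitive irradiated array, the interferon-stimulated (0.09, adjusted p = 0.14), published (0.28, 0.10), cholesterol (-0.20, 0.13) and keratinocyte lists (-0.13, 0.062) were not called, nor with scan run as a block the interferon-stimulated (0.11, 0.70), published (0.15, 0.70), cholesterol (-0.13, 0.19) and mesenchymal lists (0.15, 0.19). In chip lot 1 hypoxia had 0.39, mesenchymal genes 0.31, oxidative phosphorylation -0.16, NRF2 targets -0.13 and the proteasome -0.24. Still called with scan run as a block were hypoxia (0.33, adjusted p = 0.019) and the proteasome (-0.19, 0.00024). So were NRF2 targets (-0.20, adjusted p = 0.032), oxidative phosphorylation (-0.13, 0.0497) and keratinocyte differentiation (-0.20, 0.0497).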

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

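The 3 patterns weighed here, the comparison with markers of other cell types, the fits with the ACTB ratio as a covariate, the scan run values and the fits without the arrays that stood apart were chosen after the results were seen.

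Hypoxia response genes had a mean change of -0.36 after irradiation in the sensitive tumours. With the ACTB ratio as a covariate, as a measure of RNA quality, the mean was -0.40 (camera adjusted p = 1.6e-14). This argues against RNA quality, so far as the ratio measures it, as the whole cause. A shift that depends on intensity is argued against by random lists matched on mean signal, of which 0 were as low, with a 2.5th percentile of -0.074 and a lowest value of -0.21. Chip lot and scan run stay open: the irradiated array of the chip lot of the untreated ones had a list mean of 9.93 against 10.25 to 10.51, a fall of the mean of -0.42, and within scan run 2 the mean was -0.31, but each value rests on 1 array on a side and excludes neither. Differences in oxygen supply between the pooled tumours were not tested, and the call was lost with an estimated correlation (adjusted p = 0.081) and with fry (adjusted p = 0.053).

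Proteasome genes had a mean change of -0.18 after irradiation in the resistant tumours, whose ACTB ratios averaged 2.06 irradiated and 1.71 untreated. With this ratio as a covariate the mean was -0.13 (camera adjusted p = 0.00028), so what the ratio measures may carry a part of the change. With 1 ratio fitted, it cannot be excluded that RNA quality carries more. The GAPDH 3' to 5' ratio, 1.35 irradiated and 1.15 untreated, was not fitted. The ACTB covariate ended the call of the list in the difference of responses (median -0.19 without and -0.14 with it, adjusted p = 0.054). Without resistant irradiated array 1, which stood apart, the mean was -0.18 (-0.177, adjusted p = 4.8e-05). Of the lists matched on mean signal 0 were as low as -0.180, with a 2.5th percentile of -0.118, though the lowest reached -0.1796. The matched lists had a median of -0.044, so genes of such signal fell on balance too. A part of the change may be such a shift. The other lists called lower in these tumours had no such check. A response to radiation stays a hypothesis, as the proteasome call was lost with an estimated correlation (adjusted p = 0.38) and with fry (adjusted p = 0.13).

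Interferon-stimulated genes had a median difference of 1.70 between the untreated tumours. More host or blood cells in the resistant tumours would raise the markers of those cells too, so far as mouse transcripts bind the human probe sets. The 50 tested markers had a median of 0.0995 (bootstrap interval 0.036 to 0.27), below 0.42, a limit set as a fixed part of the interferon difference. The 39 markers of fibroblasts, endothelium, macrophages and lymphocytes had a median of 0.13 (0.036 to 0.32), but in the irradiated arrays the 50 had 0.23 (0.064 to 0.49), whose interval passed the limit of 0.45 there, and the 39 had 0.34 (0.13 to 0.60). With the ACTB ratio as a covariate the median was 1.68 (adjusted p = 3.0e-60). A difference between the tumour cells themselves may explain the pattern, as a hypothesis, while a contribution of mouse cells, seen here only by cross-hybridisation, and interferon from them acting on the tumour cells stay open.

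The test of the difference of the irradiation responses gave 9 lists for a closer look. The median differences, resistant minus sensitive, were 0.13 for interferon-stimulated genes (0.08 in the resistant and -0.03 in the sensitive response), 0.31 for the published interferon-related list (0.13 and -0.11), 0.30 for hypoxia (-0.01 and -0.30) and 0.32 for mesenchymal and invasion genes (0.06 and -0.24). They were -0.21 for NRF2 targets (-0.08 and 0.11), -0.12 for oxidative phosphorylation (-0.10 and 0.02), -0.17 for cholesterol biosynthesis (-0.14 and 0.02), -0.12 for keratinocyte differentiation (-0.05 and 0.03) and -0.19 for the proteasome (-0.15 and 0.01). None was called with an estimated correlation or with fry. With 1 array left out, the adjusted p rose to as much as 0.33 for interferon-stimulated genes (sensitive irradiated array 3), 0.12 for the published list (the same array), 0.067 for mesenchymal genes and 0.31 for oxidative phosphorylation (resistant untreated array 2), 0.15 for cholesterol biosynthesis (sensitive irradiated array 2) and 0.60 for keratinocyte differentiation (resistant irradiated array 3), while the other 3 stayed called.

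The arrays were also divided in other ways. For the difference of responses 100 splits were drawn, the real one included: 9 gave at least the 9 lists of the real split, with 11 the highest other, so chance cannot be excluded for the lists. As the real count of probe sets was 0, all 100 reached it by construction, with 2 the highest other, and the splits decide nothing there. The other comparisons allow 10 splits each, too few for a share under 0.05. Between the tumours, every other split put arrays of both tumours in each group. Their difference then widened the spread and partly stayed in the comparison, so those counts are no reference for chance. The real split and the highest other gave 1563 and 0 probe sets and 17 and 13 lists in the untreated tumours, and 1924 and 0 probe sets and 14 and 12 lists in the irradiated ones, each with 1 of 10 splits at the real count or above. They gave 1 and 9 probe sets (4 of 10 splits) and 5 and 8 lists (5 of 10) for irradiation of the resistant tumours, and 0 and 3 probe sets (10 of 10, again by construction) and 7 and 10 lists (4 of 10) for that of the sensitive. The splits with 9 and 8 probe sets in the resistant tumours put resistant untreated array 2 and resistant irradiated array 1, the arrays that stood apart, on the same side. A further 2 splits that did so gave 0, so these arrays alone do not account for the calls. Without both, the real comparison gave 29.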

How the results depend on the processing

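The scan run block, the ACTB ratio covariate and the fits without the 2 arrays that stood apart were chosen after the data were seen. Between the tumours, 78 of the 110 genes named as called in the untreated and 40 of the 103 in the irradiated arrays stayed called in every setting that tested them. So did 7 of 17 and 9 of 14 lists, while no list called in the other comparisons did. A gene with no probe set left in a setting, such as ISG15 without _x_at and _s_at probe sets, was not judged there. The median of the keratinocyte list in the difference of responses turned to 0.024 (adjusted p = 0.60) without resistant irradiated replicate 3, and was -0.22 (adjusted p = 2.8e-06) without replicate 1. UQCRB turned to -0.30 (adjusted p = 0.44) and EGFR to 0.19 (adjusted p = 0.69) in the untreated comparison without _x_at and _s_at probe sets, where another probe set stands for the gene.

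Between the untreated tumours 1563 probe sets became 954 with the scan run block and 751 without _x_at and _s_at probe sets, where fewer are tested, and 951 to 1772 with 1 array left out (951 without sensitive untreated replicate 2, 955 without replicate 3). Between the irradiated tumours 1924 became 892 with the chip lot block, 222 with the scan run block, 1229 with the ACTB covariate, 890 without _x_at and _s_at probe sets, and 1227 (without resistant irradiated replicate 3) to 2139 with 1 array left out. For irradiation of the resistant tumours the 1 probe set became 0 with quantile normalization, no filter, only the 6 arrays, no trend, no _x_at or _s_at probe sets, the chip lot block, the replicate block and the ACTB covariate, 149 with array weights and 29 without both arrays, and 0 to 105 with 1 array left out (105 without resistant untreated replicate 2, 8 without resistant irradiated replicate 2). For the sensitive tumours 0 became 5 with the scan run block and 0 to 1 with 1 array left out (1 without sensitive irradiated replicate 3). For the difference of responses 0 became 2 with the scan run block, 1 without both arrays, and 0 to 5 with 1 array left out (5 without resistant untreated replicate 2, 2 without sensitive irradiated replicate 3). With the replicate block the other counts were 1564 and 1882 between the tumours and 0 and 0.

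Lists between the untreated tumours, 17 in number, became 7 with an estimated correlation and 14 to 17 with 1 array left out, and the 14 of the irradiated 13 to 14. The 5 of the resistant response became 0 with an estimated correlation and with fry, 8 with no filter and 3 with a 60% filter, and 4 to 9 with 1 array left out (9 without resistant untreated replicate 3). The 7 of the sensitive response became 0 with an estimated correlation and with fry, 4 each with quantile normalization, no filter and a 60% filter, 3 with the scan run block, and 2 (without sensitive irradiated replicate 1) to 8 with 1 array left out. The 9 of the difference of responses became 0 with an estimated correlation and with fry, 5 with the scan run block, and 5 to 9 with 1 array left out (5 without resistant or sensitive untreated replicate 2). With the ACTB covariate the calls of double-strand break repair (0.16, adjusted p = 0.075), NF-kappaB targets (0.39, 0.11) and ribosomal proteins (-0.06, 0.11) between the untreated tumours, of fibroblast markers between the irradiated (0.27, 0.081), of NRF2 targets in the sensitive response (0.10, 0.12), and of the proteasome (-0.14, 0.054) and cholesterol biosynthesis (-0.18, 0.11) in the difference of responses were lost. Medians that stayed called but moved by over 1.5 times were, with no filter, those of the histones (-0.23 untreated, -0.29 irradiated), with a 60% filter that of hypoxia (-0.27 untreated), and with quantile normalization that of the ribosomal proteins (-0.05 irradiated). With the ACTB covariate they were those of the basal and simple epithelial genes (-0.26) and the proteasome (0.10) in the untreated, of the ribosomal proteins in the irradiated (-0.27), and of interferon-stimulated genes (0.21) and oxidative phosphorylation (-0.21) in the difference of responses. Without both arrays they were those of the ribosomal proteins (-0.24 untreated), cholesterol biosynthesis (-0.23 in the resistant response, -0.28 in the difference) and keratinocyte differentiation (-0.24 in the difference).

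Quantile normalization ended the calls of double-strand break repair (adjusted p = 0.055), NF-kappaB targets (0.063), basal and simple epithelial genes (0.063) and ribosomal proteins (median -0.01, 0.76) in the untreated, of the basal (0.063) and fibroblast lists (0.068) in the irradiated tumours, of oxidative phosphorylation in the resistant response (0.27) and the difference (0.053), and of immediate early genes (0.059), glycolysis (0.064) and macrophage markers (0.10) in the sensitive response. The last response also lost immediate early genes (0.058), NRF2 targets (0.18) and macrophage markers (0.19) with no filter. The 60% filter ended double-strand break repair (0.059), NF-kappaB (0.12) and basal genes (0.052) in the untreated, basal (0.052) and fibroblast lists (0.11) in the irradiated, G2/M (0.11), glycolysis (0.060) and oxidative phosphorylation (0.11) in the resistant response, immediate early genes (0.065) and glycolysis (0.066) in the sensitive, and keratinocyte differentiation (0.053) in the difference. The mean of all probe sets of a gene ended double-strand break repair (0.050, just above the threshold) and NF-kappaB (0.084) in the untreated, glycolysis in the resistant (0.090) and sensitive response (0.29), and the published (0.062) and keratinocyte lists (0.083) in the difference. Apart from fewer probe sets tested or arrays used, the cause was not tested. Every alternative was run where it applies. Signals near the background of 61.9 to 113 limit small differences of dim genes.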

Other observations

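The gene families below were formed after the data were seen, and the genes that bound the chromosomal stretches were named after their values were seen. Genes were grouped by the stem of their symbols, which gave 140 families of at least 8 tested genes, and tested with camera. The families overlap with the fixed lists, which hold 7 of 10 KLK, 11 of 19 keratin, 3 of 8 PARP, all 10 PSMB, 7 of 20 collagen, 7 of 17 metalloproteinase and 2 of 15 aldehyde dehydrogenase genes, but no MRPL or BMP gene, and are not separate evidence where they overlap. Kallikreins (KLK), proteases of the epidermis, had a median of -0.85 between the untreated tumours, with 7 of 10 lower in the resistant (adjusted p = 6.9e-05), and -0.89 in the irradiated ones. Keratins had -0.35 and -0.23. Poly(ADP-ribose) polymerase genes (PARP) had 0.43, with 4 of 8 higher (adjusted p = 0.0028), and 0.31, and the PSMB proteasome subunits 0.30 in the untreated tumours. In the irradiated tumours collagens had 0.50, with 4 of 20 higher, matrix metalloproteinases 0.51, with 7 of 17 higher, and aldehyde dehydrogenases -0.24, with 4 of 15 lower. Mitochondrial ribosomal proteins (MRPL) had -0.14 after irradiation of the resistant tumours and -0.13 in the difference of responses, in which bone morphogenetic proteins had 0.68 (adjusted p = 0.0041). No family was called with an estimated correlation, the adjusted p-values of those named being 0.50 to 0.93.

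Some neighbouring genes differed together between the tumours. The 7910 genes with a place were put in chromosomal order and the median difference of the untreated tumours was taken in 7470 windows of 21 genes. Of these, 16 windows lay beyond the bounds that 1000 shuffles gave (0.45 and -0.41), all 16 with the same sign in the irradiated arrays. They formed 3 stretches of overlapping windows, with 13 of the 16 in 1 stretch on chromosome 1 and 2 and 1 in the stretches on chromosome 4. On chromosome 4, the 22 genes from ABCG2 to PPA2 had a median of 0.45 in the untreated and 0.32 in the irradiated tumours, with 20 and 21 above 0, and the 21 genes from INTS12 to CCNA2 had 0.47 and 0.41, with 17 and 19 above 0. Without members of the fixed lists their medians were 0.35 and 0.43, both below the bound of 0.45 set for windows of 21 genes. On chromosome 1, the 33 genes from RFX5 to CHTOP had -0.23 and -0.33, and 13 of them belong to the fixed lists, without which the median was -0.11. A gain of a part of chromosome 4 in the resistant tumours, or a loss in the sensitive, may underlie the 2 stretches there, as a hypothesis. No copy number was measured, and genes controlled together as neighbours would give the same pattern.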
